A study of Triticum aestivum with 4 samples.

How the data were processed

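Genomic DNA of wheat seedlings was sequenced after enzymatic conversion, per the labels' protocols, which also speak of 3 biological samples per group. The library titles instead read WGBS, short for whole-genome bisulfite sequencing. The processing notes name FastQC 0.11.9, Trim Galore 0.6.7, Bismark 0.23.1 and edgeR, per the submitters' processing notes, without roles; read trimming and alignment settings, the genome build and the definition of a region are not given in the sources used here. The authors deposited 3 lists, for CpG, CHG and CHH, whose values are methylation levels in percent per region, per the file headers. The lists are named for a chi-square test and edgeR, and every region carries the value 2 for the number of lists it was found in, per the file headers. The thresholds of that selection and the coverage behind each percent value are not given in the sources used here. A selection of this kind can favour regions with large or well covered differences, so shares and medians describe the selected regions and not the genome.

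The labels name 4 libraries, 2 per group. Levels of 1 library per group were analysed here, the ultrasound library numbered 1 and a library taken as control number 1. The column of the control library carries a letter that the labels do not explain; it was assigned to the control because the lists compare it with the ultrasound column and the labels name 2 groups. If that assignment were wrong, the control side of every comparison would be wrong. The second library of each group was not analysed here. No other column of values per library was left unassigned.

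Differences are ultrasound minus control in percentage points. A region that lacked a level in at least 1 library was left out of directions and medians, which removed 414 of 3119 regions. Levels were missing in the control library for 140 CpG, 166 CHG and 59 CHH regions, and in the ultrasound library for 42, 89 and 23. Positions are those of the authors' lists. Gene identifiers and descriptions were taken from the lists; none of the 2811 identifiers matched the reference gene table, which was not used further.

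Shares of regions were given with 95% exact binomial (Clopper-Pearson) intervals and medians with order-statistic intervals, with regions as the units; intervals of a difference of shares were of the Newcombe type, built from both exact intervals. These cover counting error over regions only, and neighbouring regions are not independent. Binomial, Fisher and chi-square tests across regions had been planned, along with a test between libraries. With 1 library per group, regions cannot stand in for plants, so no p-value is reported. Gene groups were 12 sets of words matched to the descriptions. A group's median was placed among 10000 random lists of described regions of the same size, matched on context and on 5 classes of mean level. Directions of neighbours within 10 kb were compared with 1000 shuffles of direction within a context. The enrichment of regions along chromosomes was not computed, because chromosome lengths were not used here.

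The comparisons, the gene groups, the alternatives except one and the rule for named genes were fixed before the data were examined. The rule names, per context, the 5 largest increases and the 5 largest decreases, per gene group the 2 members with the largest absolute difference, and up to 10 genes listed in more than 1 context by the sum of absolute differences. Those without a description were mostly summarised. Further examples within groups, namely the methyltransferase, the histone H2A, globulin 1, the xyloglucan enzyme, the peroxidase and the psb genes, were chosen after their values were seen. Stretches were chains of regions of any context with gaps up to 10 kb and at least 4 separate loci; they, the words for organelle genes and the classes of mean level by which direction was shown were set after the data were seen.

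The alternatives were a minimum difference of 10 or 25 points, each gene counted once, regions within 10 kb merged, means in place of medians, an overlap of at least 50% of the shorter region, regions overlapping the gene only, and neighbours within 1 or 100 kb. An alternative without stretches and organelle genes was added after the data were seen.

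The computations were tested on simulated data. With directions drawn at 75% lower on the real positions, the estimates were 73.1% for 480 CpG, 74.0% for 1557 CHG and 77.2% for 668 CHH regions, each with an interval that held the true value. Directions were drawn independently for each region there, so this does not test the intervals where neighbours share a direction. For gene groups, 1000 simulated lists of 12 of the 404 described regions fell outside the central range of random lists in 4.90% of cases without a shift, in 45.8% with a shift of 10 points and in 89.0% with a shift of 20 points. A smaller run of this step had put more lists without a shift outside the range; further runs with other random seeds did not, and the number of lists was raised to 1000 after that. The computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.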

Results

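The study asked how ultrasound given to dry seeds changes DNA methylation in the seedlings that grow from them. Seeds of the winter wheat line SE15, at 13.6% water, were exposed in open dishes to 30 kHz ultrasound at 70 W for 5 min from a distance of 4 cm, or were left untreated, with 100 seeds per group. The seeds germinated in the dark at 20 °C and seedlings were taken on day 7. Per the protocols, methylation was read by enzymatic methyl-seq, in which enzymes rather than bisulfite convert unmethylated cytosines. The library titles read WGBS, and the labels do not explain the difference. The labels name 2 control and 2 ultrasound libraries, and the levels analysed here come from 1 library of each group, the control one assigned by elimination. Each value is therefore a single measurement with no replicate check, no test between the groups was run, and "lower" or "higher" below describes the ultrasound library against the control library.

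The authors' lists held 634 regions for CpG, 1745 for CHG and 740 for CHH, where H stands for A, C or T. CpG and CHG are symmetric sites and CHH is asymmetric. Every region had passed the authors' selection, named for a chi-square test and edgeR, so regions that did not pass are not in these counts. The levels given do not always show why a region was listed. Both levels were missing for 28 CpG, 67 CHG and 10 CHH regions. Some given levels were nearly equal, such as 35.4% in the control and 35.1% in the ultrasound library at a CHG region overlapping TraesCS3D02G053400. The regions were assigned to 2811 genes, at most 2997 bp away, and 441 of these genes carried a description. A level in both libraries was given for 480 CpG, 1557 CHG and 668 CHH regions. The read depth behind the levels is unknown, so the intervals below cover only the counting of regions.

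Most listed regions had less methylation in the ultrasound library, in each of the 3 contexts. In CpG, 344 of 480 regions were lower, or 71.7% (95% exact binomial interval 67.4 to 75.7). In CHG, 1218 of 1557 regions were lower, or 78.2% (76.1 to 80.3), and in CHH 515 of 668, or 77.1% (73.7 to 80.2). The median difference, ultrasound minus control, was -18.3 percentage points in CpG (95% order-statistic interval -20.1 to -16.8), -8.87 in CHG (-9.24 to -8.33) and -11.2 in CHH (-11.9 to -10.5). The mean difference in CpG was smaller in size, at -10.5 points.

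The CHG imbalance was not found among large differences. Of the CHG regions that differed by at least 25 points, 84 were lower and 68 higher, a share of 55.3% lower with an interval of 47.0 to 63.3 that includes an even split. The lower CHG regions had a median control level of 23.9%, so most of them started too low to fall by 25 points. The higher ones started at a median of 10.1%, with room to rise. The 25-point minimum can therefore leave out decreases selectively, also in the comparisons of contexts below. The share lower in CpG minus that in CHG was -6.56 points over all listed regions (interval -11.3 to -2.03) but 12.4 points (2.10 to 22.6) among regions that differed by at least 25 points. CpG minus CHH was -5.43 points (-10.7 to -0.201), and -12.3 points among the larger differences, and CHG minus CHH 1.13 points (-2.66 to 5.07), an interval that includes 0; among regions that differed by at least 25 points the latter was -24.7 points.

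CHH regions had a median level close to 0 in the library where they were lower. Among the 515 CHH regions that were lower, the median level was 14.8% in the control library and 0.638% in the ultrasound library. Among the 153 that were higher, the medians were 0.417% and 15.2%. CpG regions that were lower had medians of 53.6% and 24.5%, and those that were higher 14.5% and 61.9%. CHG regions that were lower had medians of 23.9% and 10.7%, and those that were higher 10.1% and 28.0%.

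**Figure D1:**
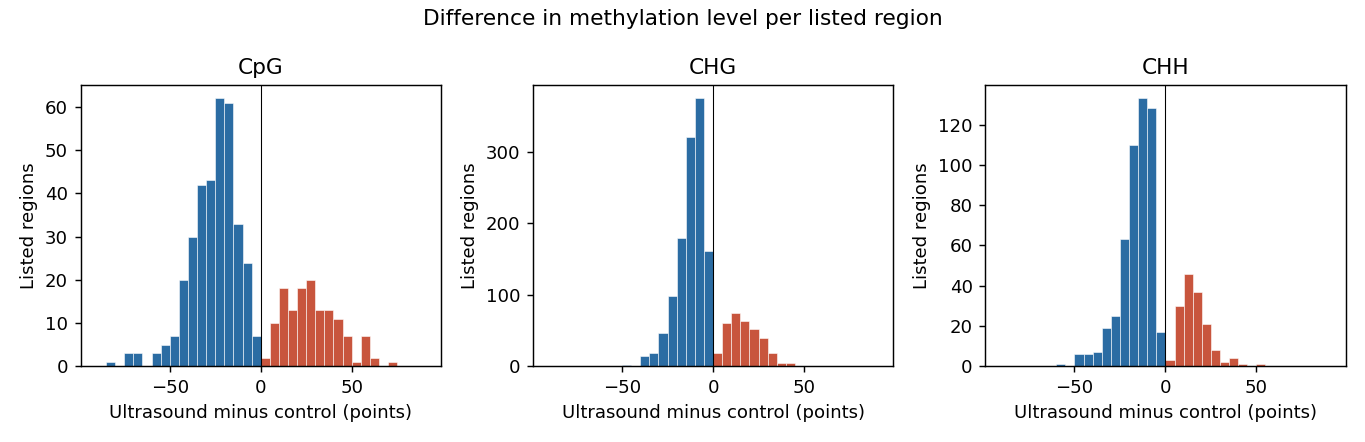
Number of listed regions (vertical axis) by the difference in methylation level, ultrasound minus control in percentage points (horizontal axis, bins of 5 points), for CpG, CHG and CHH, with a vertical scale of its own in each panel. Blue bars are regions lower after ultrasound (344, 1218 and 515) and red bars regions that were higher (136, 339 and 153).

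The largest CpG decrease lay upstream of TraesCS4B02G239700, described as similar to an HSP protein fragment, where the level was 83.3% in the control library and 1.55% in the ultrasound library (4B, 497227900 to 497228436, 691 bp from the gene). The other 4 of the 5 largest CpG decreases, with differences of -73.9 to -67.5 points, belonged to genes without a description, on 2A, 2B and 7B. The largest CpG increase covered TraesCS3B02G020500, a PAP fibrillin domain protein of a family of plastid lipid-associated proteins, with 22.2% in the control library and 97.1% after ultrasound over a region of 19077 bp (3B, 8764656 to 8783732). That region was unusually long, since listed CpG regions had a median length of 974.5 bp. The other 4 of the 5 largest CpG increases also belonged to genes without a description, among them a region downstream of TraesCS1B02G393600 listed at 0% in the control library and 58.9% after ultrasound (1B, 626242261 to 626243187).

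In CHG, none of the 5 largest differences in either direction belonged to a described gene. The largest decrease overlapped TraesCS7D02G313000, from 85.4% in the control library to 39.4% (7D, 396450649 to 396451621), and the largest increase overlapped TraesCS1B02G168700, from a listed 0% to 43.0% (1B, 299441115 to 299443949). In CHH, glutathione transferase F3 (TraesCS1D02G094700), of a family that conjugates glutathione to toxic compounds, was among the 5 largest decreases, with 53.8% in the control library and 8.24% after ultrasound in a region of 268 bp that lay 131 bp upstream of the gene (1D, 80449415 to 80449682). The 5 largest CHH increases included a region 2978 bp upstream of a pentatricopeptide repeat protein gene (TraesCS6B02G068600), a family known for RNA processing in organelles, with 0.625% in the control library and 36.5% after ultrasound (6B, 46435321 to 46435624).

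In CpG, the direction differed between classes of methylation level. CpG regions with a mean level of the libraries between 40 and 50% were lower after ultrasound in 51 of 55 cases, or 92.7%, with a lower interval bound of 82.4%. Those with a mean level above 90% were higher in 26 of 27 cases, with a median of 87.0% in the control library and 99.2% in the ultrasound library, a class that differences of over 20 points in either direction cannot enter. Between 0 and 40% the CpG share lower was 60.5% to 78.4% per class, with no steady trend. In CHG it was 77.4% to 81.7% per class between 0 and 50%, then 66.0% of 50 regions between 50 and 60% and 29.4% of 17 between 60 and 70%, the last with an interval (10.3 to 56.0) that includes an even split. In CHH it was 76.6% between 0 and 10% and 76.2% between 10 and 20%.

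**Figure D2:**
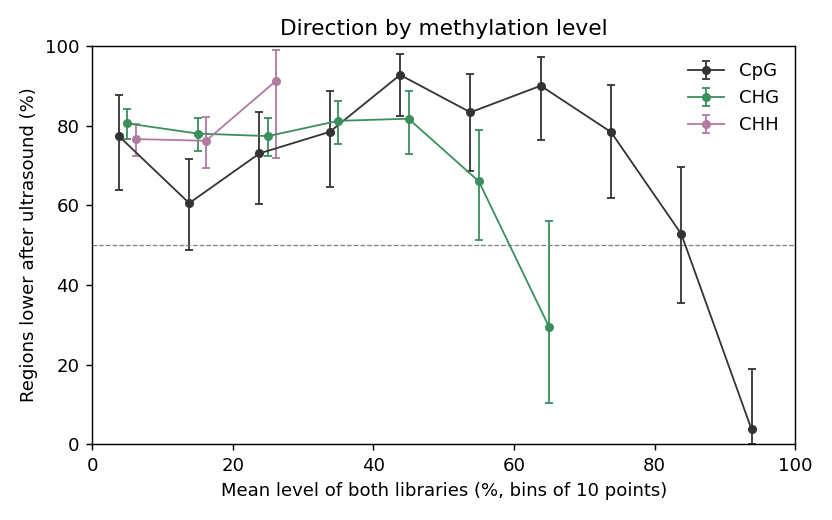
Share of listed regions that were lower after ultrasound (vertical axis, percent) by the mean level of both libraries (horizontal axis, percent, bins of 10 points), for CpG, CHG and CHH, in bins with at least 10 regions, with the contexts set slightly apart along the axis. Bars are 95% exact binomial intervals over regions and the dashed line marks 50%; in CpG the share was 92.7% between 40 and 50% and 3.70% above 90%.

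Of the 10 gene groups with at least 3 regions, the genes of DNA methylation and chromatin had the median most extreme among its random lists. Of their 14 listed regions, the 12 with levels were split evenly, with 6 higher and 6 lower. That is 50% lower with an interval of 21.1 to 78.9, which includes the 76.0% of all described regions that were lower (71.5 to 80.1). Histone genes made up 10 of the 12, with 6 lower and a median difference of -6.09 points. A methyltransferase and a SET domain gene, both higher, made up the rest. A DNA (cytosine-5)-methyltransferase gene (TraesCS4A02G102700), whose product places methyl groups on cytosine, had a CHG level of 3.91% in the control library and 19.5% after ultrasound in a region that overlapped it. Histone H4 (TraesCS6B02G078600) was at 14.6% and 51.6% in CpG in a region overlapping the gene (6B, 55121638 to 55122080), and a region 1545 bp upstream of a histone H3 gene (TraesCS1D02G364200) at 7.90% and 29.4% in CHG (1D, 445319848 to 445320461). A histone H2A gene (TraesCS7D02G246600) was lower, at 33.1% and 11.9% in CHG. The group's median difference was 5.02 points, at the 99.2nd percentile of 10000 random lists of described regions matched on context and level, but it fell in the gap between members at -5.56 and 15.6 points and its interval, -16.6 to 19.5, includes 0. With each gene counted once, over 11 genes, the median was 15.6 points. The group was the only one of the 10 groups with at least 3 regions that lay outside the central 95% of its random lists. Of simulated lists of 12 regions without a shift, 4.90% also lay outside. That rate follows from the definition of the range and holds for each list, while 10 groups were compared. The random lists could also draw regions with names of genes that organelle genomes encode, of which 53 of 54 were lower. The DNA methylation and chromatin group held no such region, and its percentile was not computed without them.

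Genes of light and the plastid were mostly lower, with 35 of 41 regions, or 85.4% (70.8 to 94.4). The largest decrease of the group overlapped an ATP synthase epsilon chain gene (TraesCSU02G251400) on unplaced sequence, at 37.0% in the control library and 10.2% after ultrasound in CHG. A chlorophyll a-b binding protein gene (TraesCS5B02G462800), which encodes a light-harvesting protein, was higher in CHH, at 0.305% and 25.3% (5B, 638336933 to 638337720). Of the 47 listed regions of this group, 27 carried names of genes that organelle genomes encode or lay in a stretch of neighbouring regions. Without those, the share lower was 60.0% (32.3 to 83.7).

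The groups tied to germination were mixed or lower. All 5 regions with levels of the genes for seed reserves were lower in CHG, led by a sucrose synthase gene (TraesCS7B02G063400), an enzyme that splits sucrose, at 58.7% in the control library and 31.3% after ultrasound (7B, 68340645 to 68342068, 1969 bp upstream). A carboxypeptidase gene (TraesCS1D02G429600) was at 38.0% and 25.8% (1D, 481324015 to 481325597), and globulin 1 (TraesCS1B02G330000), a seed storage protein, at 15.7% and 11.4%. Among hormone genes 6 of 9 regions were lower. A region 1400 bp upstream of 9-cis-epoxycarotenoid dioxygenase 2A (TraesCS5A02G374000), of the enzyme family that commits carotenoids to abscisic acid, was at 83.0% and 59.3% in CHG (5A, 572024679 to 572025531). A region downstream of the ethylene-responsive factor ERF071 (TraesCS2D02G110000) was higher in CpG, at 66.6% and 93.9% (2D, 61017532 to 61018608).

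Cell wall genes went both ways, with 7 of 11 regions lower. A laccase gene (TraesCS3D02G444900), of a family that acts in lignin formation, was at 84.6% in the control library and 39.7% after ultrasound in CpG (3D, 554217508 to 554217936). A pectinesterase gene (TraesCS1B02G477900), whose product modifies pectin, was at 94.8% and 57.3% in CpG, 2191 bp upstream (1B, 686679697 to 686680074). A xyloglucan endotransglucosylase/hydrolase gene (TraesCS3B02G108800), which remodels cell wall xyloglucan, was higher upstream in both symmetric contexts, from 49.3% to 77.7% in CpG and from 3.06% to 25.3% in CHG.

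Genes of oxidative stress were lower in 11 of 17 regions. Ascorbate peroxidase 4 (TraesCS2D02G434500), an enzyme that removes hydrogen peroxide, was higher in CHG in a region overlapping the gene, at 25.2% in the control library and 55.5% after ultrasound (2D, 545847353 to 545848194). A peroxidase gene (TraesCS3D02G185000) was higher upstream in CpG, from 6.10% to 34.6%, and in CHG, from 8.42% to 22.2%. The words for mechanosensing, calcium and membrane channels matched no gene described as mechanosensitive. The members with levels were phospholipases, calcium-transporting ATPases, potassium transporters and glutamate receptors, and 7 of 8 regions were lower. A potassium transporter gene (TraesCS6A02G063000) had the largest difference of that group, from 50.3% to 13.2% in CHG (6A, 33587996 to 33590561). A phospholipase D gene (TraesCS5A02G202000) was its single higher member, at 71.8% in the control library and 26.1 points higher after ultrasound in CpG (5A, 408844912 to 408845209).

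DNA repair and cell cycle genes were lower in 8 of 9 regions, including a DEAD-box RNA helicase gene matched by the word helicase. The mismatch repair gene MSH7 (TraesCS3B02G136600) was at 78.4% and 39.1% in CHG in a region overlapping the gene (3B, 119464308 to 119465308), and an ATP-dependent DNA helicase gene (TraesCS4D02G144400), the single higher member, was at 8.24% and 34.0% in CHG 923 bp downstream (4D, 132772249 to 132773648). The transcription factor group was lower in 7 of 8 regions, with a WRKY gene (TraesCS5D02G190800) at 22.4% and 5.17% in CpG (5D, 293162777 to 293163621). Its lower members include a zinc finger protein gene and a RING/FYVE/PHD-type zinc finger gene. Both were matched only by the words zinc finger, and their descriptions do not name a transcription factor. Heat shock and dehydration genes were lower in 2 of 4 regions. They included a heat stress transcription factor gene similar to Spl7 (TraesCS5D02G244800), at 30.4% and 16.7% in CHG (5D, 353475447 to 353476803). The defence group held 1 region, upstream of a defensin gene (TraesCS5A02G329100), an antimicrobial peptide, at 1.66% and 27.0% in CpG (5A, 538002879 to 538003940). No listed gene matched the transposon group. Apart from the DNA methylation and chromatin group, the medians of the 9 groups with at least 3 regions lay within the central 95% of their random lists, from the 18.5th percentile for light and plastid to the 87.0th for heat shock and dehydration.

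**Figure D3:**
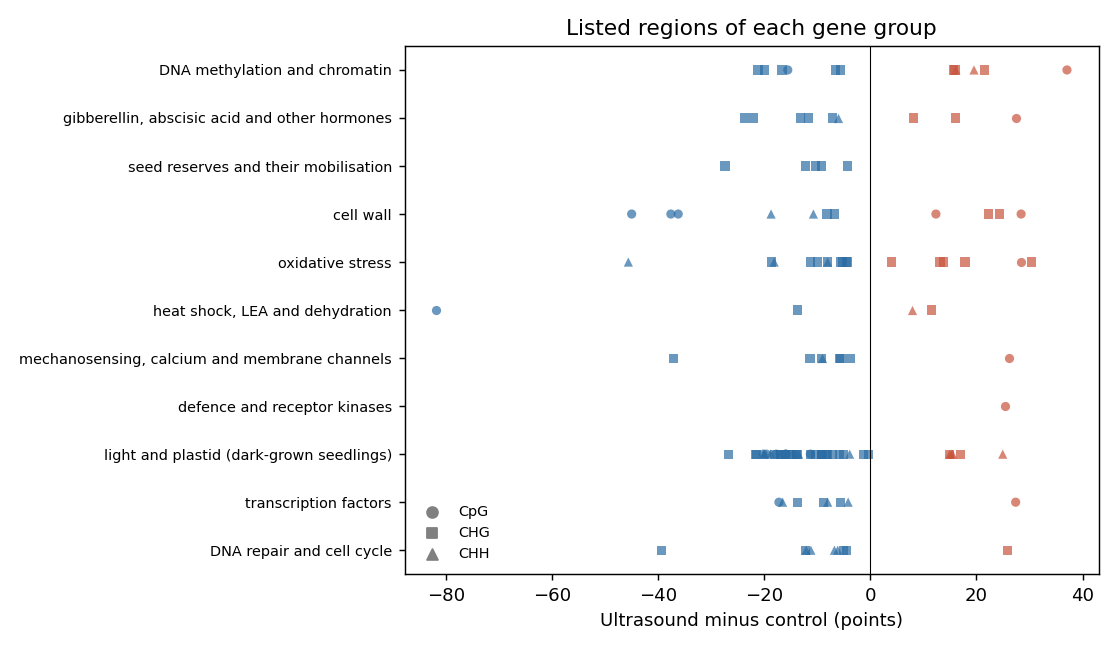
Difference in methylation level, ultrasound minus control in percentage points (horizontal axis), of every listed region of each gene group with a level in both libraries. Each point is 1 region, blue where lower and red where higher; circles are CpG, squares CHG and triangles CHH. The DNA methylation and chromatin group had 6 points on each side, and the light and plastid group 35 of 41 on the lower side.

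Where CpG and CHG regions overlapped, they almost always differed in the same direction. Of 148 overlapping pairs with levels, 146 had the same direction (98.6%, interval 95.2 to 99.8), with 133 lower and 13 higher in both contexts. Both contexts compare the same pair of libraries at the same loci, so this agreement is no independent check of a direction. CHH regions rarely overlapped the others, with 7 pairs with CpG and 13 with CHG. A gene for the cytochrome b559 alpha subunit (TraesCS6A02G020700), a photosystem II protein, was among the 10 genes with the largest summed differences, with a CHG region overlapping the gene at 61.2% and 24.2% (6A, 9649381 to 9654704) and a CpG region downstream at 82.1% and 16.6% (6A, 9656215 to 9660280). The other 9 of these genes carried no description, and all 10 were lower in each listed context. The cytochrome b559 gene carried a name of a gene that organelle genomes encode. TraesCS7B02G396200, TraesCS5D02G345100 and TraesCS7B02G395400 lay in stretches of neighbouring regions, which are treated below. Ranking by a sum also favours genes with several listed regions. Among the 150 genes with levels in more than 1 context, 123 were lower throughout, 16 higher throughout and 11 mixed.

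Most regions with levels were lower in each of the A, B and D subgenomes of hexaploid wheat, and differences between subgenomes were not tested. In CHG, 80.1% of A regions (76.2 to 83.6), 74.7% of B regions (70.6 to 78.5) and 80.5% of D regions (77.0 to 83.8) were lower. In CpG the shares were 73.3%, 72.1% and 70.6%, and in CHH 76.6%, 77.1% and 77.8%. Regions overlapped their gene in 59.8% of CHG, 54.3% of CpG and 28.1% of CHH cases. Chromosome 5D held the most CHG regions with levels, 126, of which 108 were lower. Its count includes 12, 9, 5 and 6 CHG regions in stretches of neighbouring regions, treated below, and all of these were lower.

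Listed CHG regions with a listed neighbour within 10 kb, 300 of 1557 or 19.3%, mostly shared its direction. Of 200 neighbouring CHG pairs, 192 had the same direction, against 110 to 152 in 1000 shuffles of the directions. In CpG it was 33 of 35 pairs (10 to 30 in shuffles), and in CHH 7 of 10 pairs, inside the shuffled range of 1 to 10. A set of 20 stretches with at least 4 neighbouring loci, defined after the data were seen, held 166 regions. Of the 164 with levels 162 were lower, and both exceptions lay on 7D between 231553859 and 231569939.

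The stretch with the most regions, on 2B from 474895280 to 474925528, held 17 regions at 9 genes without a description, with a median level of 43.6% in the control library and 21.5% after ultrasound. A stretch on 5D from 6162515 to 6210854 carried the photosystem II genes psbM (TraesCS5D02G007700), at 32.3% and 18.5% in CHG, and psbI (TraesCS5D02G008000), at 30.8% and 19.5%. Genes with names that plastid or mitochondrial genomes encode occurred in 7 of the 20 stretches. Over all listed regions with such names and levels, 53 of 54 were lower. These genes were recognised by description alone, and some such descriptions also fit nuclear genes.

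**Figure D4:**
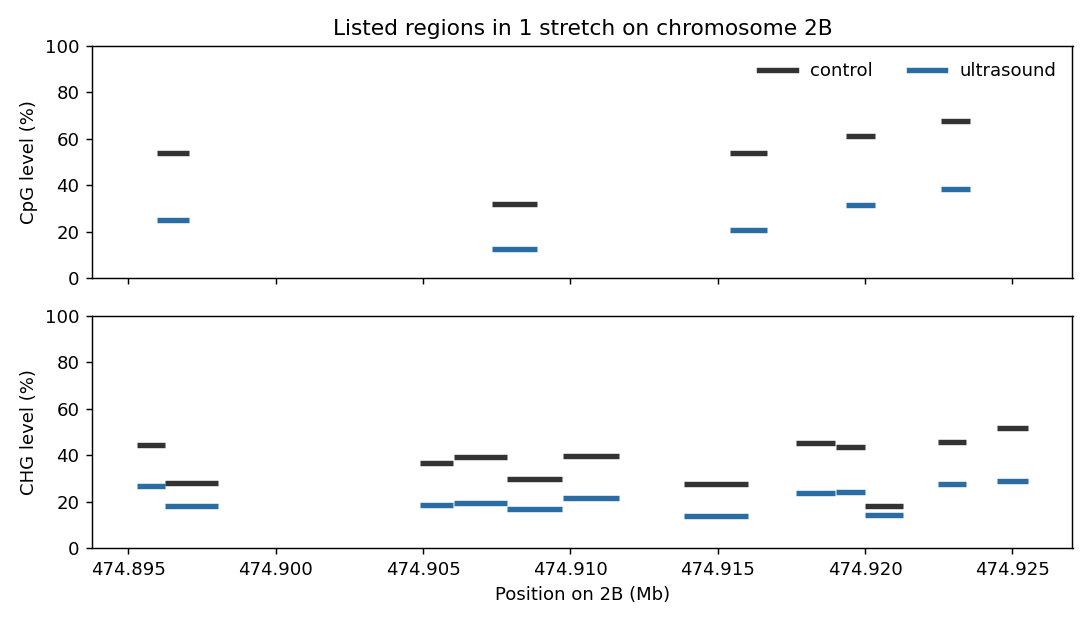
Methylation level in percent (vertical axis) of the 17 listed regions in the stretch on chromosome 2B, by position in megabases as the authors' lists give it (horizontal axis), CpG above and CHG below. Each bar spans 1 region, black for the control and blue for the ultrasound library, and the ultrasound level was the lower one in each of the 17.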

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

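The alternative without stretches and organelle genes was chosen after seeing the data; the others were planned. No paired analysis was possible because only 1 library per group had levels. For the same reason leaving out a replicate was not run, and neither were stricter p thresholds, coverage minimums, Fisher tests on counts or a model on logit values, since p-values, coverage and counts were not used here. Depth limits on single regions are therefore unknown. Of 151 values under alternatives, 121 stayed within the interval or count range of the reported value, 29 moved and 1 reversed a difference whose interval excluded 0. The sign changed in 4 of the values: CpG minus CHG at 25 points, which is the reversed one, and CHG minus CHH, whose interval included 0, at 25 points, with neighbours merged (-1.44) and without stretches and organelle genes (-1.03). The share of regions lower in a context ranged from 55.3% to 80.0% over the alternatives. The 121 values that stayed within include ones with little room to leave. The share of heat shock and dehydration genes had an interval of 6.76 to 93.2. A fall from 148 to 100 overlapping CpG and CHG pairs still counted as within range. In several gene groups an alternative removed no region, so the share could not move.

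Regions that differed by at least 25 points left 157 lower and 75 higher in CpG, 84 and 68 in CHG, and 64 and 16 in CHH, with 55.3% lower in CHG. The CpG share minus the CHG share then turned to 12.4 points, CpG minus CHH was -12.3 and CHG minus CHH -24.7; the cause was not tested. At 10 points, CHG kept 682 lower regions (72.5%). Merging within 10 kb gave 75.5% lower in CHG and 77.0% in its D subgenome. Means were -10.5 points in CpG, -6.04 in CHG and -8.53 in CHH. Without stretches and organelle genes, CHG was 76.0% lower with a median of -8.20, and the light and plastid group 60.0%. Regions overlapping the gene gave 100% lower for DNA repair and cell cycle; groups left with fewer than 3 regions were not given. An overlap of 50% left 2 pairs of CpG and CHH. The share of regions with a neighbour was 5.42%, 12.3% and 1.35% within 1 kb and 19.2%, 22.5% and 5.24% within 100 kb, for CpG, CHG and CHH, and 8.58% for CpG and 11.4% for CHG without stretches.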

Other observations

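All tests in this part were chosen after the results were seen, and so were the genes and the 8 gene families looked at here. In the 8 tests of technical explanations, the reading of 5 changed once values were known, from excluded to open for a loss of like proportion, and from met to open for a noisier control library at the ends of the scale. The test at intermediate levels was run first on CpG and CHG together, where 58.3% of 410 regions outside stretches and organelle genes were lower (53.4 to 63.1), which decided nothing, and was split by context after that. Incomplete conversion was read first as excluded, then as open because the regions that spoke against it were all listed as higher, and then as excluded again, since choosing regions cannot give a level under a floor. In between, its test was replaced by a difference between libraries in the share of CHH regions under 1% where they are lower, 75.8% in control and 64.1% after ultrasound, or 11.7 points (3.10 to 19.6), whose outcome was foreseeable, and the first test was then restored. The ratio of CpG to CHG was first to count for dilution by organelle DNA, and was read as undecided once the same ratio was found outside the stretches.

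Some genes outside the fixed groups stood out by their levels. A region of 9723 bp over MFT-3B-1 (TraesCS3B02G010100), a gene of the MFT family known for seed dormancy, was at 0.833% in the control library and 34.5% after ultrasound in CpG (3B, 4734475 to 4744197), while a CHG region over MFT-3B-2 (TraesCS3B02G007400) was listed without a level in either library. The MFT-3B-1 region was far longer than the median of 974.5 bp for listed CpG regions. A region upstream of a glutamine synthetase gene (TraesCS4D02G240700), an enzyme of ammonium assimilation, was at 11.9% and 61.6% in CpG, and a CHH region overlapping another (TraesCS4A02G266900) at 21.2% and 1.64%. A gene described as ABA Overly-Sensitive 5 (TraesCS6D02G178700) went from 96.0% to 50.5% in CpG. Exocyst subunit Exo70 genes, of a family that acts in secretion, had 6 listed regions, 4 lower and 2 higher. Hexosyltransferase genes were lower in 10 of 11 regions, protein DETOXIFICATION genes in 5 of 6, dirigent protein genes in 4 of 5 and CASP-like protein genes in 2 of 5. The peroxidase and histone genes, which belong to fixed groups, were lower in 10 of 15 and 6 of 10 regions. Among all described regions 76.0% were lower, and the interval of each of these families includes that share. For hexosyltransferase genes it was 58.7 to 99.8.

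The stretches of neighbouring regions were nearly all lower, 162 of 164. A candidate explanation is a larger share of unmethylated organelle DNA in the ultrasound library, with organelle reads placed on nuclear copies of organelle genes. Such names outside the stretches were lower in 97.6% of 41 regions (87.1 to 99.9), against 74.2% (72.2 to 76.2) of other CpG and CHG regions, as that would give. Dilution should scale CpG and CHG alike, and the ratio of ultrasound to control differed by -0.0283 between them over 43 overlapping pairs in stretches (-0.0778 to 0.0405), but also by only -0.00952 over 85 lower pairs elsewhere, so this test leaves it open. A response of these loci to ultrasound is also open, untested with 1 library per group. In 13 of the 20 stretches there was no organelle name. That says little, because only 441 of the 2811 listed genes carried a description at all.

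Most listed regions were lower in the ultrasound library, and 4 technical explanations were weighed. Single events counted many times are argued against, since without stretches and with neighbours merged the lowest share over the contexts, in CpG, was 68.0% (63.2 to 72.4). A noisier control library would scatter regions at an ultrasound level of 30 to 70% to both sides. Outside stretches and organelle genes, 70.9% of 148 such CpG regions were lower (62.9 to 78.1), and 51.1% of 262 CHG regions (44.9 to 57.3). Choosing regions by the ultrasound level itself moved these shares. By mean level instead, the CHG share lower was 78.9% between 30 and 40% and 79.5% between 40 and 50%. It was 64.4% between 50 and 60%, but 29.4% of 17 regions between 60 and 70%. The CpG shares in these classes were 73.2%, 90.9%, 81.6% and 88.9%. In CpG most regions were thus lower by either choice, which goes against an even scatter there. For CHG the choices disagreed, so a noisier control library stays open. Incomplete conversion across the control library would need a floor of about 13.7% under every CHH level to give the median loss. It is argued against at that size by the 17.4% of CHH regions with a control level under 1% (14.6 to 20.5). A smaller floor, or one at some regions, stays open, and the coverage behind these levels is unknown. The test of a loss of like proportion at every level could not decide. Of CpG regions with a mean level above 90%, 3.70% were lower (0.0937 to 19.0). A loss of the median proportion leaves a mean of at most 72.8% and cannot enter that class. The proportion was not alike across contexts: medians of lower regions went from 53.6% to 24.5% in CpG but from 14.8% to 0.638% in CHH. How far the authors' selection shaped this is unknown, so a like proportion within a context stays open. A treatment effect may remain, but it was not tested, and the authors' selection of regions stays open too.

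CpG levels above 98% were held more often by the ultrasound library. Of 34 CpG regions with exactly 1 library above 98%, the ultrasound library held that level in 26, or 76.5% (58.8 to 89.3), and within direction it was above 98% in 19.1% of the higher regions and the control library in 2.33% of the lower ones. At the lower end, the ultrasound library alone was under 1% in 52 CpG regions and the control library alone in 38, a share of 57.8% (46.9 to 68.1), while within direction the control library was under 1% in 27.9% of the higher regions and the ultrasound library in 15.1% of the lower ones, a difference of 12.8 points (4.35 to 21.9). A control library that is noisier through lower coverage could account for the upper end, but at the lower end the count includes an even split and the shares go the other way, so with the coverage unknown it stays open. A gain of methylation at such regions after ultrasound was not tested, and levels were missing in the control library alone for 260 regions and in the ultrasound library alone for 49.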
